A study of Mus musculus with 12 samples.

How the data were processed

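RNA was measured in 12 libraries from mouse embryonic stem cells in which the ribosomal protein Rpl31 carried a FLAG tag, a TEV protease site and an AviTag. Per the labels' protocols, plasmids encoding the N-terminal and C-terminal fragments of the ALIBi biotinylation system were transfected, biotinylated ribosomes were affinity purified from lysates containing cycloheximide, and RNA was extracted from the TEV eluate and from an aliquot of lysate set aside before purification. Libraries were made from poly(A) RNA with a directional kit, 9 cycles of PCR and paired-end sequencing, per the labels' protocols. The labels place each library in 1 of 4 groups by targeting (cytosol or endoplasmic reticulum, ER) and fraction (ribosome-bound or whole-cell), with 3 biological replicates in each group. The labels call the replicates biological without naming separate cultures or days, so p-values measure the spread between these samples. The siRNA treatment that the series' design text mentions for some cells is not a label of any of these libraries.

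The deposited values are whole-number read counts per Ensembl gene, not normalized, in 1 file per library. Per the submitters' processing notes, reads were handled with STAR 2.7.9a and HTSeq 0.11.2 on GRCm39, and DESeq2 was used, with no version given. The annotation release, the strand setting of the counter and the handling of multimapped reads are not given in the sources used here. Counts of antisense genes, of genes that overlap another gene and of members of near-identical families are therefore uncertain. Among the genes named in the text this applies to the Zscan4 family, to Mars and Ddit3, which overlap, and to ribosomal protein genes, which have many processed pseudogenes. The files list 55416 gene identifiers and 5 class totals for reads outside genes, which held 8.8% to 12.5% of the reads per library and were kept out of library sizes and tests. Reads aligned to more than 1 place made up 4.92% to 5.11% of reads in the ER ribosome-bound libraries, 5.58% to 6.17% in the cytosol ribosome-bound libraries and 7.25% to 7.58% in the whole-cell libraries.

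Gene names, gene types, coding lengths and protein sequences came from the GENCODE M21 annotation, which is built on GRCm38, so no coordinates were taken from it and none are printed. It matched 52083 of the identifiers, and the 3333 without a match held 0.41% of the counts. Symbols follow that release (Mars, Yars, Ddx58).

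Reads counted in genes came to 21.1 to 26.9 M per library; intervals and errors in the text cover counting error and the spread between replicates as the model estimates it, not amplification by PCR. Genes were kept with filterByExpr by group, leaving 16221, and scaled with trimmed mean of M values (TMM) factors. One model with the 4 groups and no further term was fitted to all 12 libraries with edgeR 4.0.16 in R 4.3.3, and each of 5 comparisons was tested, 2-sided, with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over all tested genes at 0.05. Levels in CPM (counts relative to the scaled library size) are TMM-scaled, and changes are log2 ratios with a standard error (SE). The SE was derived as the absolute log2 ratio over the square root of the quasi-likelihood F statistic. The 5 comparisons were ER ribosome-bound against cytosol ribosome-bound, ribosome-bound against whole-cell within each targeting, ER whole-cell against cytosol whole-cell, and the difference between both enrichments over whole-cell RNA. The biological coefficient of variation was 3.6%. Replicates of a group were compared before use. Their log2 CPM correlated across genes at 0.9968 to 0.9981, genes being no independent replicates, and all pairs differed by more than counting noise, with a chi-square per gene of 2.11 to 9.1. The highest value belonged to cytosol whole-cell replicates 1 and 2. As a mean over genes, it can rest on a few genes with high counts. In this pair a gene without a symbol in the annotation used was at 3340.6 and 10060.6 CPM.

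The procedure was tested on simulated counts for 16221 genes with 50 genes changed at each size. As many genes were raised as lowered in total, so errors of scaling when changes go mostly in a single direction are not covered. For ER against cytosol ribosome-bound RNA, 64% of genes changed 1.25-fold, 72% at 1.5-fold, 90% at 2-fold and 100% at 4-fold were recovered, with 7 false calls. For ER ribosome-bound against whole-cell RNA the shares were 64%, 74%, 88% and 100% with 8 false calls, and for the difference of enrichments 42%, 60%, 86% and 98% with 10. The list test called 10 of 10 simulated lists of 30 genes shifted by 0.3 (log2) and 0 of 10 unshifted lists. Simulated genes varied independently, so this does not cover lists whose genes vary together. The estimated correlation reached 0.656 for the ribosomal protein list.

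The comparisons, tests, alternatives, rule for named genes and 29 gene lists with 698 genes were fixed before the data were examined. The lists cover the ER translocon and N-glycosylation machinery, ER chaperones, secreted and basement membrane proteins, plasma membrane receptors, solute carriers, GPI-anchored proteins, lysosomal proteins, Golgi proteins, lipid enzymes of the ER membrane, cytosolic sterol enzymes, tail-anchored proteins, unfolded protein and integrated stress response targets, interferon-stimulated genes, glycolytic enzymes, ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, proteasome subunits, cytosolic chaperones with cytoskeleton, nuclear-encoded respiratory chain subunits, mitochondrially encoded proteins, nuclear noncoding RNAs, pluripotency regulators, nuclear envelope membrane proteins, and markers of endoderm, mesoderm, neural and epiblast cells, fibroblasts and the 2-cell-like state. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera asks whether a list's genes moved relative to all other genes. Members past the threshold were counted over all genes tested and adjusted over the list alone.

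Proteins were also sorted into 6 classes by hydrophobic segments, predicted from mean Kyte-Doolittle hydropathy. A segment was a window of 19 residues with a mean of at least 1.6, or, within the first 30 residues, of 11 residues with a mean of at least 2. The predictor does not separate signal peptides from membrane anchors or from mitochondrial targeting sequences, and it misses some signal peptides. It also finds internal segments in cytosolic proteins, such as Cct8, Fasn and Psmd2.

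Named genes were chosen by rule. In each comparison these were the 8 protein-coding genes with the largest and the 8 with the most negative change among those past the threshold, with a mean of at least 10 CPM and the same direction in all 3 same-numbered pairs of replicates. Added to them were Rpl31 and, for each list, up to 3 changed members with the largest absolute change and the member nearest 0, each with a mean of at least 10 CPM. The text names fewer than the rule gives, and genes outside it are said to be chosen after their values were seen.

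Alternatives were size factors of DESeq2 (RLE) in place of TMM, TMM factors from 5 fixed lists of cytosolic proteins (glycolytic enzymes, translation factors, proteasome subunits, synthetases, and cytosolic chaperones with cytoskeleton; called cytosolic scaling below), leaving out mitochondrially encoded genes, DESeq2 1.42.0, limma-voom, no filter on low counts, a minimum of 5 CPM in 3 libraries, fitting only the groups compared, a block for the replicate number, a test against a 2-fold change, and leaving out each library and each replicate number. Lists were also tested with an estimated correlation and with fry, which asks whether a list's genes move one way without comparing them with other genes. Camera with an estimated correlation for the hydrophobic segment classes was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.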

Results

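The libraries measured poly(A) RNA of mouse embryonic stem cells of the E14Tg2a.4 line, whose ribosomes carried a tagged Rpl31, a protein of the large subunit. ALIBi, a biotinylation system expressed as N-terminal and C-terminal fragments, marked ribosomes in the cytosol or at the ER, and the marked ribosomes were purified with their mRNAs. RNA of the whole lysate served as input. Each of the 4 groups (cytosol or ER targeting, ribosome-bound or whole-cell RNA) held 3 biological replicates. Reads counted in genes came to 23.3 to 25.1 M per library in cytosol ribosome-bound RNA, 23.4 to 26.9 M in ER ribosome-bound RNA, 23.4 to 25.5 M in cytosol whole-cell RNA and 21.1 to 26.8 M in ER whole-cell RNA. The first principal component, with 68.2% of the variance over 9612 genes, placed the ER ribosome-bound libraries at 51.08 to 51.44 and the other 9 libraries between -19.66 and -15.28. The second, with 28.6%, placed the cytosol ribosome-bound libraries at -32.12 to -29.57 and the whole-cell libraries at 15.04 to 16.82.

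Rpl31, the gene that carried the tag, was read in every library. Its mean level was 966.5 ± 18.6 CPM (SD, n = 3) in cytosol ribosome-bound RNA, 1056.3 ± 6.9 CPM in ER ribosome-bound RNA, 1142.3 ± 35.8 CPM in cytosol whole-cell RNA and 1122.5 ± 37.5 CPM in ER whole-cell RNA. Rpl31 mRNA was lower on cytosol-labelled ribosomes than in whole-cell RNA, with a log2 change of -0.24 (SE 0.033, adjusted p = 1.2e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its other differences were small, and whether they passed the threshold depended on the libraries fitted or on scaling. On ER-labelled ribosomes the 3 libraries lay at 1052 to 1064 CPM, above the 946 to 983 CPM of the cytosol-labelled ones. ER-labelled over cytosol-labelled ribosomes gave 0.13 (SE 0.033), and this was no longer past the threshold without cytosol ribosome-bound replicate 2, without any 1 of the cytosol whole-cell or ER ribosome-bound replicates, or without ER whole-cell replicate 2 or 3 (0.06 to 0.07), nor with mitochondrially encoded genes left out (0.07). Whole-cell libraries enter that comparison only through the shared scaling and fit. ER-labelled ribosomes over whole-cell RNA gave -0.09 (SE 0.033), which became 0.16 with cytosolic scaling. This difference was not past the threshold without ER ribosome-bound replicate 3 (-0.08) or ER whole-cell replicate 2 (-0.06).

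The comparison of both ribosome-bound groups asked which mRNAs were translated at the ER and which in the cytosol. mRNAs of proteins that enter the secretory pathway were higher on ER-labelled ribosomes, and those of most cytosolic and nuclear proteins differed little. Ddost, a subunit of the oligosaccharyltransferase that glycosylates nascent proteins, led the genes named, at 719 ± 12.1 CPM (SD, n = 3) on ER-labelled and 113.1 ± 5.7 CPM on cytosol-labelled ribosomes, a 6.36-fold difference (log2 2.67, SE 0.037). Psap, the precursor of the lysosomal saposins, reached 2393.1 ± 20.8 CPM against 399.3 ± 16 CPM, or 5.99-fold. Bsg, a plasma membrane glycoprotein that escorts lactate transporters, was 6.09-fold higher, the lysosomal and secreted growth factor precursor Grn 5.99-fold, the GPI transamidase subunit Pigs 5.94-fold, the prohormone Trh 5.91-fold, the cargo receptor Lman1 5.90-fold and the Golgi glycoprotein Glg1 5.88-fold. Differences in the other direction were smaller. Zscan4c, a marker of the 2-cell-like state from a family of near-identical genes, had a log2 change of -0.74 (SE 0.080), Rcc1, the exchange factor of Ran on chromatin, -0.66 (SE 0.045), Dlat, a subunit of pyruvate dehydrogenase, -0.63 (SE 0.037), and Lmnb2, a lamin, -0.63 (SE 0.047).

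Of 16221 genes tested, 4715 were higher and 3984 lower on ER-labelled ribosomes. A change of over 2-fold was found in 2940 of the former and 19 of the latter. Scaling to cytosolic proteins in place of all genes raised the median log2 ratio by 0.199 and gave 7301 higher and 933 lower genes, so small differences, above all small decreases, depend on the scaling. Tested against a 2-fold change with glmTreat of edgeR, 2317 genes were higher and 0 lower (6 lower at an unadjusted p under 0.05).

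**Figure D1:**
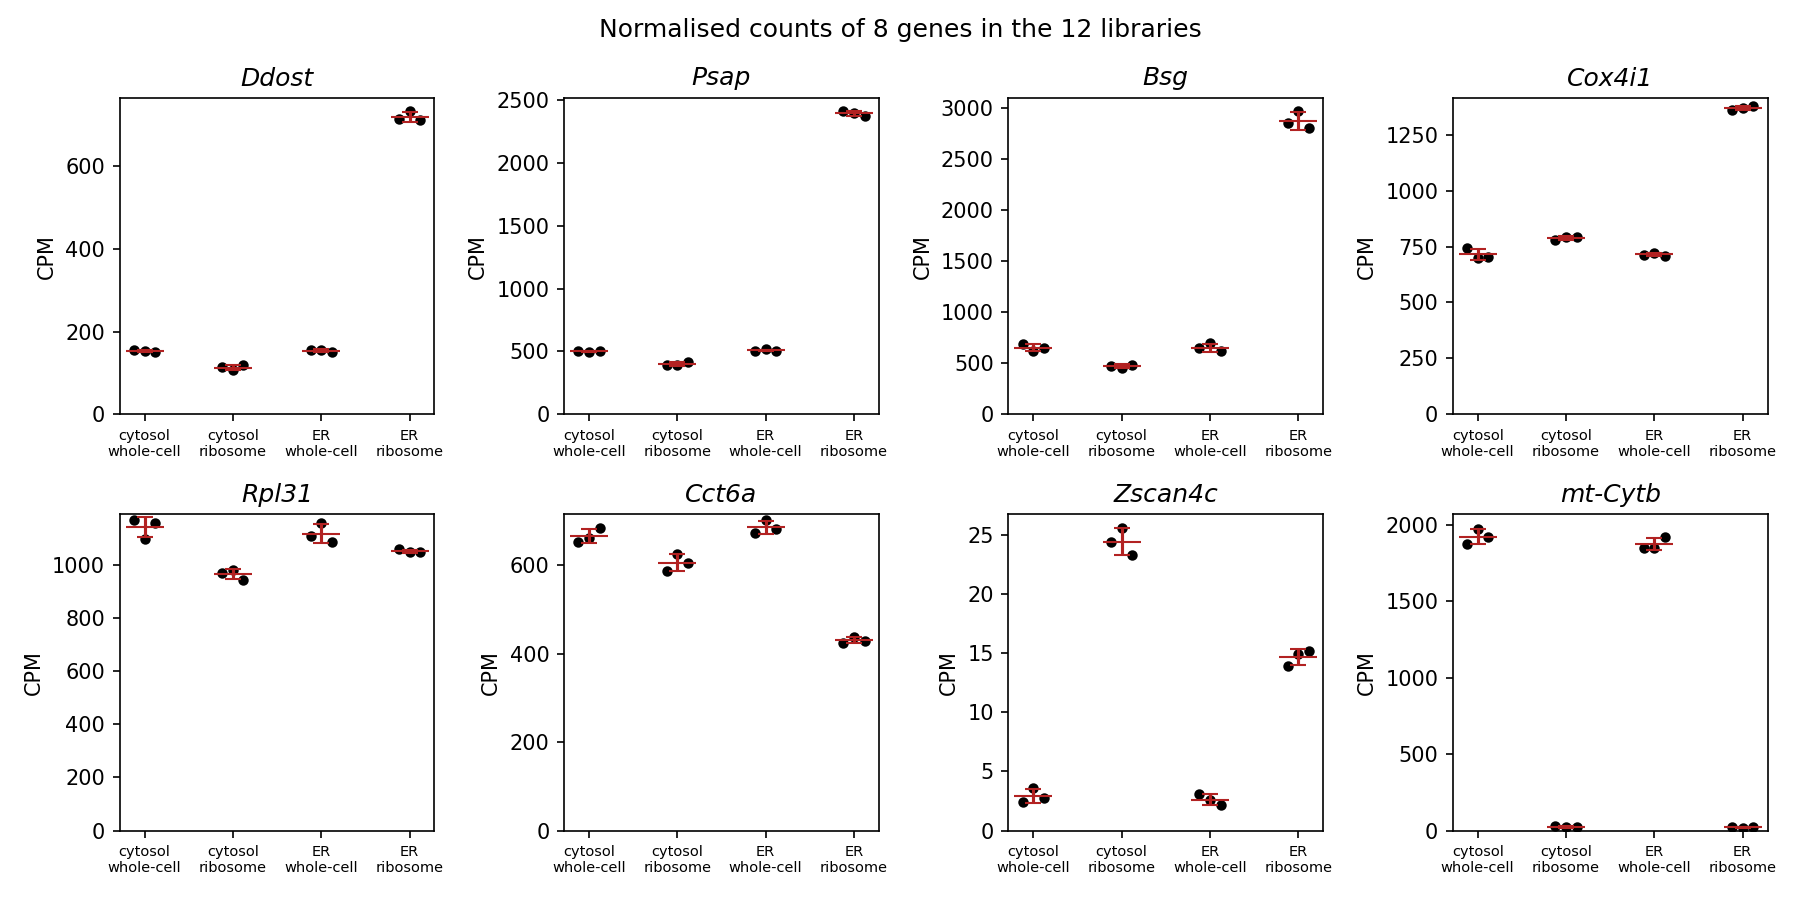
Each panel shows the TMM-scaled CPM of 1 gene in the 12 libraries, with a point per library and the mean and SD of the 3 replicates of each group in red. Ddost, Psap, Bsg and Cox4i1 were highest in the ER ribosome-bound libraries, Cct6a was lowest there, Zscan4c was higher in both ribosome-bound groups than in whole-cell RNA, and mt-Cytb was near 0 on ribosomes.

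All measured members of 9 lists of ER-translated proteins were higher on ER-labelled ribosomes, and the counts were the same when adjusted over the list alone. These were 30 of 30 translocon and N-glycosylation genes (median log2 1.89), 32 of 32 ER chaperones and folding enzymes (2.25), 33 of 33 secreted and basement membrane proteins (2.01), 38 of 38 plasma membrane receptors (1.96), 27 of 27 solute carriers (1.58), 15 of 15 GPI-anchored proteins (1.91), 30 of 30 lysosomal proteins (2.26), 26 of 26 Golgi proteins (1.78) and 27 of 27 lipid enzymes of the ER membrane (1.69). Among ER chaperones, the disulfide isomerases Pdia6 and Pdia3 had log2 changes of 2.51 (SE 0.040) and 2.48 (SE 0.036). Spp1, a secreted phosphoprotein, reached 2.49 (SE 0.041), the lipoprotein Apoe 2.45 (SE 0.042), the heparan sulfate proteoglycan Gpc3 2.56 (SE 0.042), the integrin Itgb1 2.3 (SE 0.036), the amino acid transporter Slc7a5 2.17 (SE 0.037) and the sterol reductase Dhcr7 2.26 (SE 0.037). The members nearest 0 stood well below their lists, with 0.59 (SE 0.033) for the ribosome-binding membrane protein Lrrc59, 0.50 (SE 0.038) for squalene synthase Fdft1, 0.80 (SE 0.056) for the large receptor Lrp1 and 1.06 (SE 0.048) for Vegfa. Of 14 nuclear envelope membrane proteins, 12 were higher and 1 lower (median 1.64), with Nrm at 2.08 (SE 0.049), the nucleoporin Nup210 at 2.07 (SE 0.051) and the giant linker protein Syne2 at 0.14 (SE 0.106), not past the threshold. The counts of this list did not change when adjusted over the list alone. Camera's adjusted p was 7.2e-09 for the nuclear envelope list and between 1.7e-31 and 7.6e-13 for the other 9, and with an estimated correlation it was 0.00049 to 0.0071 over these 10 lists.

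**Figure D2:**
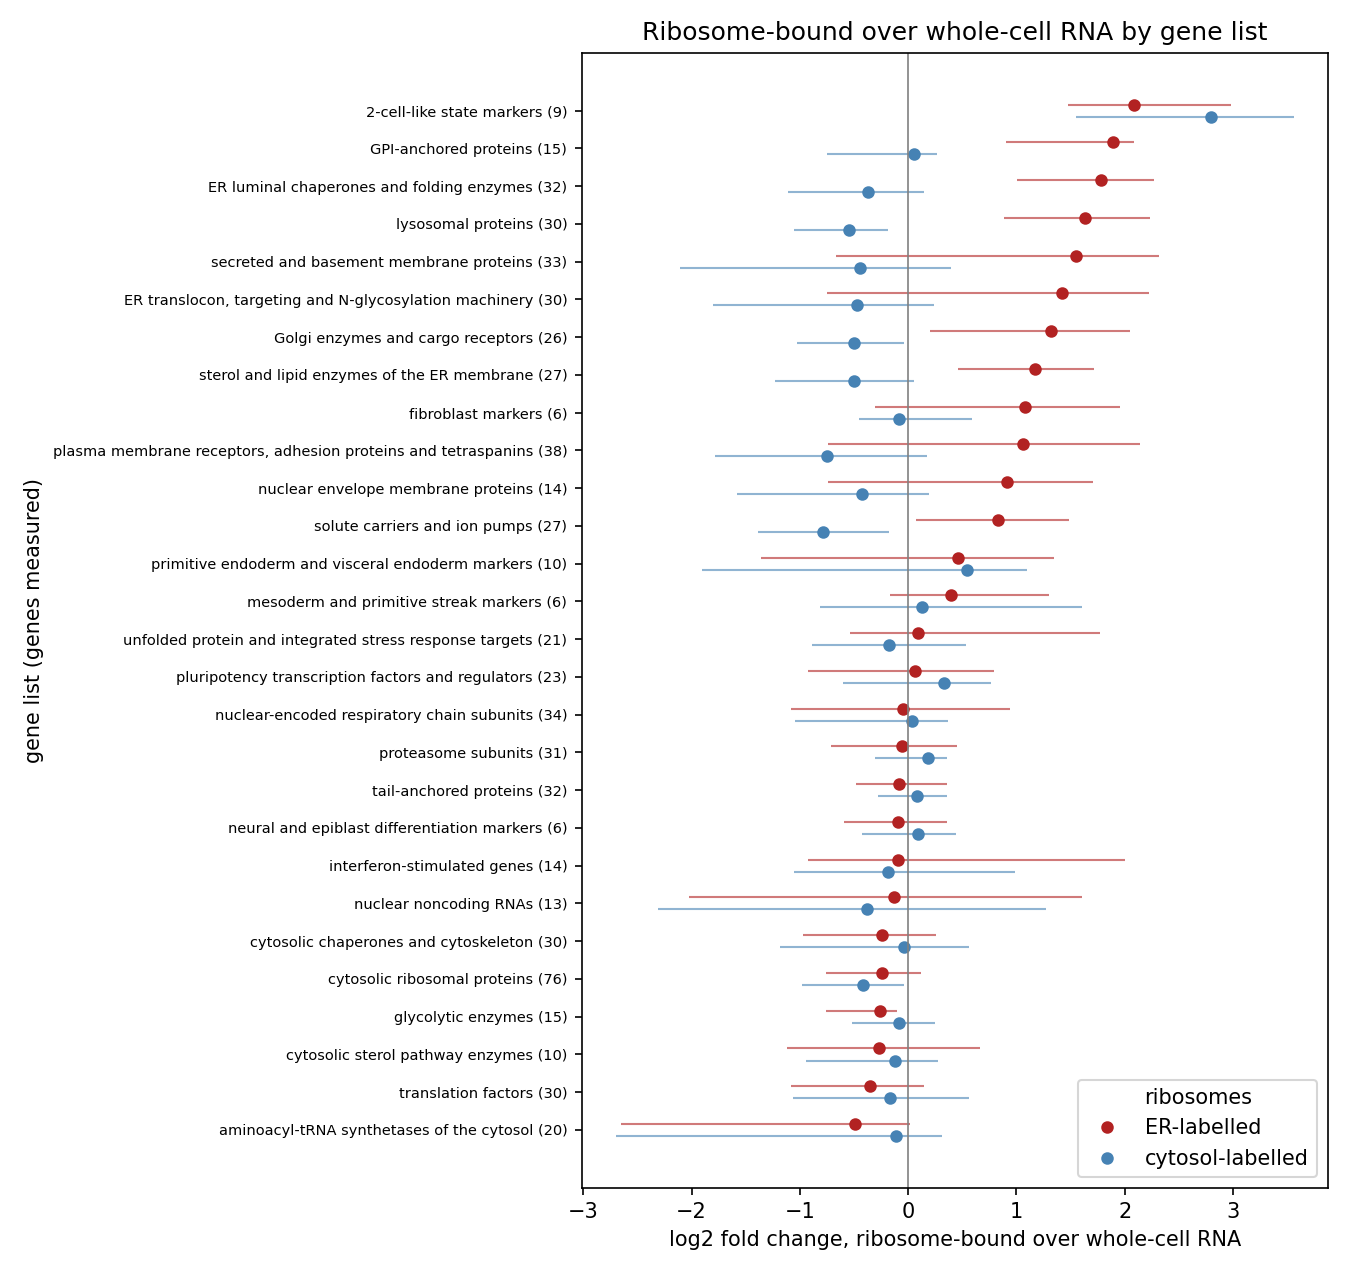
For each gene list (number of genes measured in brackets), the dot is the median and the line the range of its members' log2 fold change of ribosome-bound over whole-cell RNA, in red for ER-labelled and in blue for cytosol-labelled ribosomes; the mitochondrially encoded list is left out. ER chaperones had medians of 1.78 and -0.37, and markers of the 2-cell-like state 2.09 and 2.8.

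Lists of cytosolic proteins had small shifts. Cytosolic scaling is defined by the glycolytic, translation factor, proteasome, synthetase and cytosolic chaperone lists, so their medians lie near 0 with it by construction, and it shows only that their shifts are relative to the reference chosen. Aminoacyl-tRNA synthetases, which charge tRNAs, were lower for 16 of 20 and higher for 1 (17 and 1 when adjusted over the list alone; median -0.29, or -0.09 with 9 lower and 4 higher under cytosolic scaling), and this was the only lower list still called with an estimated correlation (adjusted p = 0.041). Yars had a log2 change of -0.48 (SE 0.033). Proteasome subunits were lower for 24 of 31 and higher for 2, both over all genes and adjusted over the list alone (median -0.23, or -0.03 with 11 lower and 7 higher under cytosolic scaling; adjusted p = 5.3e-08 with the preset and 0.081 with an estimated correlation). They were led by the ATPase subunit Psmc5 at -0.46 (SE 0.039). The median of 30 cytosolic chaperone and cytoskeleton genes was -0.19 and became 0.00 with cytosolic scaling, with 20 lower and 3 higher over all genes and adjusted over the list alone (11 and 12 under cytosolic scaling; adjusted p = 8.6e-07, and 0.11 with an estimated correlation). In that list the chaperonin subunit Cct6a was at -0.49 (SE 0.034) and Actb at -0.41 (SE 0.037). Glycolytic enzymes had a median of -0.16 that turned to 0.04 with cytosolic scaling, 11 of 15 being lower (11 lower and 1 higher when adjusted over the list alone, 6 and 4 under cytosolic scaling; adjusted p = 1.8e-04, and 0.24 with an estimated correlation), Tpi1 among them at -0.35 (SE 0.033). Translation factors had a median of -0.09 that turned to 0.11 with cytosolic scaling and was -0.15 with mitochondrially encoded genes left out, with 15 of 30 lower and 8 higher (17 and 8 when adjusted over the list alone, but 7 and 16 under cytosolic scaling; adjusted p = 0.012, and 0.41 with an estimated correlation). The helicase Eif4a1 was at -0.41 (SE 0.033). Pluripotency regulators had a median of -0.18 that turned to 0.02 with cytosolic scaling, 15 of 23 being lower (17 when adjusted over the list alone, but 3 lower and 9 higher under cytosolic scaling; adjusted p = 7.6e-05, and 0.081 with an estimated correlation). Dppa2 was at -0.49 (SE 0.056) and the nuclear receptor Esrrb at -0.33 (SE 0.037).

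Cytosolic ribosomal protein mRNAs went the other way. Of 76 genes, 69 were higher on ER-labelled ribosomes (70 when adjusted over the list alone) and none was lower by edgeR's test, with a median of 0.17. It was 0.37 with cytosolic scaling, 0.13 with RLE size factors and 0.11 with mitochondrially encoded genes left out. Rpl18 reached 0.37 (SE 0.035) and the stalk protein Rplp1 0.32 (SE 0.035), while Rpl7a stood at -0.01 (SE 0.034), or 0.19 with cytosolic scaling. Camera's adjusted p was 1.9e-06, and 0.48 with an estimated correlation.

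Tail-anchored proteins, whose single membrane anchor lies at the C terminus and is inserted after translation, had a median of -0.14 that turned to 0.06 with cytosolic scaling. Of 32 measured, 19 were lower (20 when adjusted over the list alone, but 4 lower and 9 higher under cytosolic scaling; adjusted p = 1.9e-04, and 0.091 with an estimated correlation), among them the ER-bound phosphatase Ptpn1 at -0.37 (SE 0.049) and the mitophagy receptor Bnip3l at -0.35 (SE 0.041). Markers of the 2-cell-like state were lower for 6 of 9 (7 when adjusted over the list alone; median -0.59, or -0.39 with 3 lower under cytosolic scaling; adjusted p = 0.012, and 0.16 with an estimated correlation).

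The remaining lists were not called. Nuclear-encoded respiratory chain subunits were higher for 7 and lower for 18 of 34 (8 and 19 when adjusted over the list alone), with a median of -0.10 that became 0.10 with cytosolic scaling, where 22 were higher and 2 lower. Without the replicates numbered 2 or 3 the list was called, at -0.17 and -0.16. Cox4i1, a subunit of cytochrome c oxidase, stood apart at 0.80 (SE 0.032) and Ndufa4, associated with the same complex, at 0.71 (SE 0.040). Cytosolic sterol enzymes were higher for 2 and lower for 7 of 10, also when adjusted over the list alone, but for 3 and 3 under cytosolic scaling (median -0.25, then -0.05). Acetyl-CoA carboxylase Acaca was at 0.83 (SE 0.048) and Hmgcs1 at -0.36 (SE 0.040). Targets of the unfolded protein and integrated stress responses were higher for 10 and lower for 7 of 21 in both counts (12 and 1 under cytosolic scaling), and the higher ones named by the rule encode secretory pathway proteins, the ER degradation factors Sel1l at 2.14 (SE 0.050) and Edem1 at 1.71 (SE 0.045) and the lipoprotein receptor Vldlr at 2.17 (SE 0.093). Interferon-stimulated genes were higher for 4 and lower for 2 of 14 (3 and 2 when adjusted over the list alone, 6 and 1 under cytosolic scaling), with the membrane protein Ifitm3 at 1.29 (SE 0.041). Nuclear noncoding RNAs were higher for 7 of 13, also when adjusted over the list alone, and for 12 under cytosolic scaling, with Tug1 at 0.48 (SE 0.043) and Malat1 at 0.45 (SE 0.091). Of 12 mitochondrially encoded mRNAs, only mt-Co1 was past the threshold, also when adjusted over the list alone, at 0.21 (SE 0.045), and not without cytosol ribosome-bound replicate 2 (0.11) or ER ribosome-bound replicate 3 (0.09). Lineage markers were sparse. Endoderm markers were higher for 2 and lower for 1 of 10 (2 and 0 when adjusted over the list alone), with a median of -0.11 (0.09 with cytosolic scaling) against a mean of 0.27 and an upward test. Mesoderm markers were lower for 1 of 6, with a median of -0.14 (0.06 with cytosolic scaling), a mean of 0.07 and a downward test. Neural and epiblast markers were lower for 2 of 6 with a median of -0.15 (0.05 with cytosolic scaling), including the methyltransferase Dnmt3b at -0.54 (SE 0.041). Fibroblast markers were higher for 3 of 6, including the GPI-anchored Thy1 at 1.86 (SE 0.063). The counts of these 3 lists did not change when adjusted over the list alone.

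The hydrophobic segments of the encoded protein separated the genes. With an N-terminal segment and at least 1 further segment, 1259 of 1401 genes were higher on ER-labelled ribosomes and 81.7% were over 2-fold higher (median log2 1.56, camera adjusted p = 3.1e-61). With an N-terminal segment alone, as in secreted proteins, 916 of 1200 were higher and 62.8% over 2-fold higher (median 1.38, adjusted p = 1.6e-30). Proteins with at least 2 internal segments and none at the N terminus had 908 of 1169 genes higher (median 1.11, adjusted p = 1.3e-28). A single internal segment gave 440 higher and 249 lower of 1224 (median 0.06, adjusted p = 0.28), and a single segment at the C terminus 80 higher and 84 lower of 330 (median 0.01, adjusted p = 0.50). Genes without a segment had 890 higher and 3433 lower of 8790, with a median of -0.12 that turned to 0.08 with cytosolic scaling (adjusted p = 3.4e-36). With an estimated correlation the 3 classes with medians above 1 kept adjusted p values of 1.2e-06 or less, and the class without a segment 1.8e-08. Stricter thresholds for a segment moved the median of the single internal class to 0.50 and of the C-terminal class to 0.11, both then called. The single internal class mixed cytosolic proteins such as Cct8 (-0.43, SE 0.033) with ER membrane proteins such as Dhcr7 (2.26, SE 0.037). Its median therefore does not describe membrane proteins alone.

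**Figure D3:**
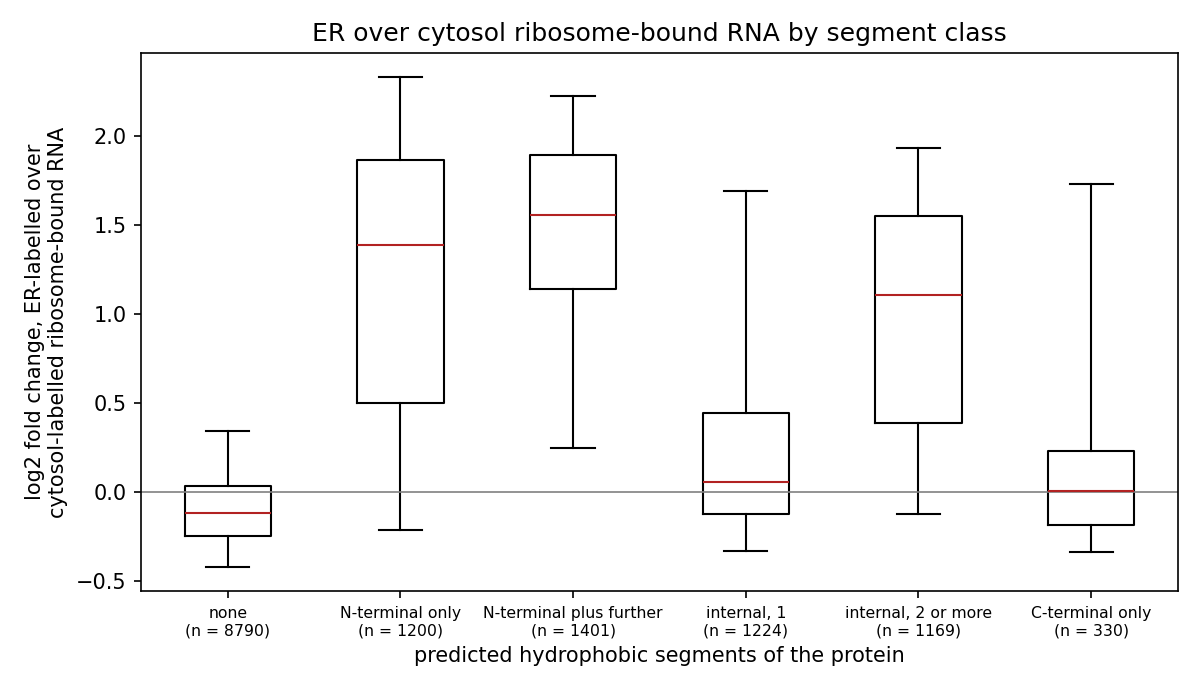
Boxes show the quartiles and median (red) and whiskers the 5th and 95th percentiles of the log2 fold change of ER-labelled over cytosol-labelled ribosome-bound RNA, by class of predicted hydrophobic segments (number of genes in brackets). The medians were 1.38, 1.56 and 1.11 in the N-terminal and multiple internal classes and between -0.12 and 0.06 in the other 3, where that of genes without a segment turned to 0.08 with cytosolic scaling.

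Set against whole-cell RNA of cells with the same targeting, ER-labelled ribosomes were enriched for the same kinds of secretory mRNAs and depleted of mitochondrially encoded ones. The protease inhibitor Serpine2 was 6.47-fold higher than in whole-cell RNA (log2 2.69, SE 0.055), at 117.8 ± 4.7 CPM (SD, n = 3) against 18.1 ± 1.4 CPM. Pcsk1n, an inhibitor of a prohormone convertase, was 5.22-fold higher, the receptor chaperone Lrpap1 5.09-fold and Apoe 4.99-fold. Zscan4c was 5.61-fold higher, from 2.6 ± 0.5 to 14.7 ± 0.7 CPM. Mitochondrially encoded mRNAs, which are translated by mitochondrial ribosomes, were nearly absent from the ribosome-bound RNA, with mt-Cytb at 21.1 ± 1.8 CPM against 1873.6 ± 40.5 CPM (log2 -6.48, SE 0.071).

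Of the tested genes, 5271 were higher and 4967 lower on ER-labelled ribosomes than in whole-cell RNA, of which 2674 and 312 by over 2-fold. Cytosolic scaling raised the median log2 ratio by 0.247 and gave 8430 higher and 2257 lower. Lists higher were translocon genes (29 of 30 with 1 lower, median 1.42), ER chaperones (32 of 32, 1.78), secreted proteins (30 of 33 with 1 lower, 1.55), receptors (36 of 38 with 1 lower, 1.06), solute carriers (25 of 27, 0.83), GPI-anchored proteins (15 of 15, 1.89), lysosomal proteins (30 of 30, 1.63), Golgi proteins (25 of 26, 1.32), lipid enzymes of the ER membrane (27 of 27, 1.17) and nuclear envelope proteins (12 of 14 with 2 lower, 0.91). These counts were the same when adjusted over the list alone, except 26 Golgi proteins, and the 10 calls held with an estimated correlation (adjusted p = 0.0011 to 0.026). Creld2 and Pdia6 led the chaperones at 2.27 (SE 0.041) and 2.25 (SE 0.039), and Igfbp2 reached 2.26 (SE 0.038) among secreted proteins. Among members nearest 0, the laminin Lama5 was at -0.03 (SE 0.037; 0.22 with cytosolic scaling), the receptor Igf2r at 0.03 (SE 0.034), and the folding sensor Uggt1 at 1.01 (SE 0.045). All 9 measured 2-cell-like markers were higher, also when adjusted over the list alone (median 2.09, adjusted p = 0.0042, and 0.12 with an estimated correlation).

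Lower on ER-labelled ribosomes than in whole-cell RNA were all 12 mitochondrially encoded mRNAs (median -5.90) and 19 of 20 aminoacyl-tRNA synthetases (median -0.49, or -0.25 with 14 lower and 2 higher under cytosolic scaling), in both counts and with an estimated correlation (adjusted p = 0.011 for each). Of the synthetases, Mars was at -2.65 (SE 0.049), a gene that overlaps Ddit3. Ribosomal proteins had 68 of 76 lower and 2 higher, also when adjusted over the list alone, with a median of -0.24 that became 0.01 with cytosolic scaling (20 lower and 26 higher; adjusted p = 6.3e-14, and 0.31 with an estimated correlation). Rplp0 was at -0.76 (SE 0.034). Translation factors were lower for 26 of 30 and higher for 3 in both counts (median -0.35, or -0.10 with 17 lower and 7 higher under cytosolic scaling; adjusted p = 0.070 with an estimated correlation), with the poly(A)-binding protein Pabpc1 at -0.83 (SE 0.032). All 15 glycolytic enzymes were lower in both counts (median -0.26, or -0.01 with 7 lower and 6 higher under cytosolic scaling; adjusted p = 0.14 with an estimated correlation). Cytosolic chaperones and cytoskeleton were lower for 22 of 30 and higher for 3 in both counts, with a median of -0.24 that became 0.01 with cytosolic scaling (11 lower and 14 higher; adjusted p = 0.14 with an estimated correlation), and Myh9, the heavy chain of nonmuscle myosin, was at -0.97 (SE 0.041). The other 12 lists were not called. Interferon-stimulated genes had a median of -0.09 (0.16 with cytosolic scaling), a mean of 0.21 and a downward test. Within uncalled lists, the fatty acid synthase Fasn was at -1.12 (SE 0.042), Xbp1 at 1.29 (SE 0.049), the succinate dehydrogenase subunit Sdha at -1.08 (SE 0.037) and Cox4i1 at 0.94 (SE 0.032).

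Cytosol-labelled ribosomes, set against their own whole-cell RNA, had lower levels of mRNAs of most lists of secretory proteins. The ribosome-binding ER protein Rrbp1 was at -1.80 (SE 0.044), the oligosaccharyltransferase subunit Stt3a at -1.53 (SE 0.049), the laminin Lama1 at -2.11 (SE 0.087), Igf2r at -1.78 (SE 0.038), the transferrin receptor Tfrc at -1.49 (SE 0.041) and the drug exporter Abcc1 at -1.39 (SE 0.038). Several of these have long coding sequences, and among genes without a hydrophobic segment the median enrichment on cytosol-labelled ribosomes was 0.12 for 575 genes with up to 0.5 kb of coding sequence and -1.05 for 33 genes with over 8 kb. The 2-cell-like marker Zscan4c was 8.35-fold higher than in whole-cell RNA (log2 3.06, SE 0.106), at 24.4 ± 1.1 CPM (SD, n = 3) against 2.9 ± 0.6 CPM. The splicing-related factor Bclaf1 was 2.72-fold higher, the calcium-binding protein S100a6 2.10-fold, the transcription factor Jun 2.08-fold, the secreted protease inhibitor Serpine2 2.05-fold and the 14-3-3 protein Sfn 2.01-fold. Mitochondrially encoded mt-Cytb was at -6.36 (SE 0.070).

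On cytosol-labelled ribosomes 3381 genes were higher and 5360 lower than in whole-cell RNA, of which 312 and 594 by over 2-fold. Lower lists were plasma membrane receptors (36 of 38, median -0.75), solute carriers (27 of 27, -0.79), translocon genes (27 of 30 with 2 higher, -0.47), ER chaperones (29 of 32 with 2 higher, -0.37), Golgi proteins (25 of 26, -0.50) and lipid enzymes of the ER membrane (26 of 27, -0.50), with adjusted p of 0.013 to 0.024 with an estimated correlation. The 12 mitochondrially encoded mRNAs were also lower (median -5.98, adjusted p = 0.019 with an estimated correlation). For lysosomal proteins (30 of 30, -0.55), secreted proteins (23 of 33 with 2 higher, -0.44) and nuclear envelope proteins (10 of 14 with 2 higher, -0.43), the adjusted p with an estimated correlation was 0.052, 0.052 and 0.051. Ribosomal proteins were lower for 74 of 76 (median -0.42, adjusted p = 3.8e-28, and 0.14 with an estimated correlation), Rplp0 at -0.98 (SE 0.034). Translation factors were lower for 19 of 30 and higher for 6 (median -0.17, or -0.11 with mitochondrially encoded genes left out) and synthetases lower for 11 of 20 and higher for 3 (median -0.11, or -0.05 without those genes), with adjusted p of 0.38 and 0.27 with an estimated correlation. Pabpc1 was at -1.06 (SE 0.032) and Mars at -2.70 (SE 0.049).

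Higher on cytosol-labelled ribosomes than in whole-cell RNA were all 9 markers of the 2-cell-like state (median 2.8, adjusted p = 0.019 with an estimated correlation). Proteasome subunits were higher for 23 of 31 and lower for 2 (median 0.18, adjusted p = 4.8e-07, and 0.11 with an estimated correlation), Psmc4 at 0.36 (SE 0.036). Pluripotency regulators were higher for 15 of 23 and lower for 5 (median 0.33, adjusted p = 2.6e-06, and 0.052 with an estimated correlation), among them the transcription factors Nanog at 0.65 (SE 0.032) and Tbx3 at 0.74 (SE 0.040). Tail-anchored proteins were higher for 13 of 32 and lower for 4 (median 0.08, or 0.13 with mitochondrially encoded genes left out; adjusted p = 0.0027, and 0.16 with an estimated correlation). Adjusted over the list alone, the counts of the lists called in this comparison were the same except 25 lower secreted proteins and 7 higher translation factors. The other 12 lists were not called. Among them the GPI-anchored list had a median of 0.05, a mean of -0.03 and an upward test, cytosolic chaperones and cytoskeleton a median of -0.04, a mean of -0.07 and an upward test, and fibroblast markers a median of -0.08, a mean of 0.01 and an upward test. Respiratory chain subunits, at 0.04, were called with cytosolic scaling (0.07) and without the replicates numbered 3 (0.12). The imprinted noncoding RNA Rian was at -2.31 (SE 0.055) and Malat1 at 1.27 (SE 0.099).

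Whole-cell RNA of cells with ER-targeted and cytosol-targeted ALIBi gave no gene past the threshold. By edgeR's quasi-likelihood test 0 genes passed, with 634 at an unadjusted p under 0.05, and DESeq2 and limma-voom also gave 0. Ddost was at 154.2 ± 2.8 and 153.3 ± 2.1 CPM (SD, n = 3), and Zscan4c at 2.6 ± 0.5 and 2.9 ± 0.6 CPM. With no filter on low counts 7 genes were lower by edgeR's test, named here after their values were seen. They were Lars2 (-0.80), Mir6236 (-0.80), Gm15564 (-0.83), Rpph1 (-1.48) and 3 genes without a symbol in the annotation used (-1.97 to -0.77). All 7 were highest among whole-cell libraries in cytosol replicate 2, with Lars2 at 929.6 CPM there and 277.4 to 355.2 CPM in the other 5. Without cytosol whole-cell replicate 3, 2 genes passed as lower, the RNase P RNA Rpph1 at -1.88 (8.7 CPM in cytosol replicate 2) and a gene without a symbol in the annotation used at -2.03, both named after their values were seen. Camera called 4 lists as higher by 0.02 to 0.08 (median), namely solute carriers, lysosomal proteins, translation factors and nuclear noncoding RNAs (adjusted p = 0.032 to 0.035, and 0.74 for each with an estimated correlation), with no member past the threshold in edgeR's test over all genes. Adjusted over the list alone, only the hexokinase Hk2 of the glycolytic list was higher, at 0.14 (SE 0.042). Without the replicates numbered 2 none of these 4 was called, and lysosomal proteins and translation factors were at -0.02 and -0.01. Median, mean and test differed in sign for 7 of the lists, none of them called.

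The difference between both enrichments, which sets each ribosome-bound group against its own whole-cell RNA, was led among the genes named by Ddost. It had a log2 difference of 2.66 (SE 0.052), and others named were Bsg at 2.61 (SE 0.058), the membrane protein Susd2 at 2.57 (SE 0.087), Psap at 2.56 (SE 0.047) and the adhesion molecule Bcam at 2.53 (SE 0.054). The most negative named genes included the transcriptional cofactor Srfbp1 at -0.68 (SE 0.074), the gene AI661453 at -0.67 (SE 0.101), Lmnb2 at -0.66 (SE 0.066), the RNA-binding proteins Myef2 and Taf15 at -0.65 (SE 0.064 and 0.091), Dlat at -0.64 (SE 0.051) and the ribosome biogenesis factor Krr1 at -0.62 (SE 0.068). Enrichment was greater on ER-labelled ribosomes for 4023 genes and greater on cytosol-labelled ribosomes for 3010, of which 2849 and 33 by over 2-fold. Cytosolic scaling raised the median by 0.221 and gave 6123 and 468. The Rpl31 difference of 0.15 (SE 0.047, adjusted p = 0.0073) was not past the threshold without cytosol ribosome-bound replicate 2 (0.11), cytosol whole-cell replicate 1 (0.08) or 3 (0.09), ER ribosome-bound replicate 1 (0.09), 2 (0.10) or 3 (0.11), or ER whole-cell replicate 3 (0.08). Among gene lists whose enrichment was not called as different, endoderm markers had a median difference of -0.17, a mean of 0.17 and an upward test, and mesoderm markers -0.04, 0.32 and a downward test. With cytosolic scaling these medians turned to 0.05 and 0.18.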

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

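The enrichment over whole-cell RNA was compared between ER-labelled and cytosol-labelled ribosomes by a test of the difference itself, and 18 gene lists and Rpl31 differed. The tests of scaling, coding length and carried-over RNA for the ribosomal protein list were chosen only after the result was seen; the list tests were planned.

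Enrichment was greater on ER-labelled ribosomes for 10 lists of proteins made at the ER or placed in its membrane, and these calls held with an estimated correlation. The median log2 difference was 1.86 for the translocon and N-glycosylation machinery (30 of 30 higher), 2.25 for ER chaperones (32 of 32), 2.03 for secreted proteins (32 of 33), 1.91 for plasma membrane receptors (38 of 38), 1.54 for solute carriers (27 of 27), 1.9 for GPI-anchored proteins (14 of 15), 2.23 for lysosomal proteins (30 of 30), 1.84 for Golgi proteins (26 of 26), 1.67 for lipid enzymes of the ER membrane (27 of 27) and 1.62 for nuclear envelope proteins (12 of 14 higher, 1 lower).

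Enrichment was lower on ER-labelled ribosomes for 7 lists, 5 of which define cytosolic scaling and so lie near 0 with it by construction (all but the tail-anchored and pluripotency lists). Of the 7, the synthetases alone held with an estimated correlation (16 of 20 lower and 1 higher, median -0.31, adjusted p = 0.036), though with cytosolic scaling its median was -0.09 with 6 lower and 4 higher. The median was -0.24 for proteasome subunits (24 of 31 lower and 1 higher, adjusted p = 0.086 with an estimated correlation) and -0.02 with cytosolic scaling, with 8 lower and 5 higher. It was -0.16 for tail-anchored proteins (15 of 32 lower, adjusted p = 0.094 with an estimated correlation) but 0.06 with cytosolic scaling (1 lower, 5 higher), and -0.19 for glycolytic enzymes (10 of 15 lower, adjusted p = 0.21 with an estimated correlation) but 0.03 with that scaling (3 lower, 4 higher). It was -0.11 for translation factors (14 of 30 lower and 6 higher, adjusted p = 0.35 with an estimated correlation) but 0.11 with cytosolic scaling (6 lower, 14 higher), where the list was not called. Cytosolic chaperones and cytoskeleton (20 of 30 lower) and pluripotency regulators (15 of 23 lower) had medians of -0.23 and -0.22 that both became 0.00 with cytosolic scaling, with 5 lower and 10 higher and with 2 lower and 4 higher (adjusted p = 0.098 and 0.086 with an estimated correlation). Adjusted over the list alone, the counts of all these lists were the same except 16 lower translation factors and 21 lower and 2 higher chaperone and cytoskeleton genes. Rpl31 differed by 0.15, a call lost with RLE size factors (0.11), with mitochondrially encoded genes left out (0.10) and in 9 of 15 fits without a library or replicate number.

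Ribosomal protein mRNAs were more enriched on ER-labelled ribosomes by a median of 0.18, or 0.40 with cytosolic scaling, 0.14 with RLE size factors and 0.13 with mitochondrially encoded genes left out (57 of 76 higher, 64 when adjusted over the list alone; adjusted p = 0.53 with an estimated correlation), and by 0.08, not called, without the replicates numbered 3. Scaling shifts all genes alike, and between ER-labelled and cytosol-labelled ribosomes, on which these tests were run, the list lay 0.30 above 6187 other genes without a hydrophobic segment, with 0.28 to 0.33 over the 9 pairs of single libraries. Short coding sequences were tested against 2735 genes of the same coding length range, above which the list lay 0.32 (library pairs 0.31 to 0.34). Only the range was matched, not the distribution of lengths. Genes without a segment had a median of -0.07 with up to 0.5 kb and -0.16 with 0.5 to 1 kb, against 0.17 for the list. More whole-cell RNA in the ER purification would have raised mitochondrially encoded mRNAs, whose median over 12 genes was -0.02 (library pairs -0.44 to 0.41). These values argue against the 3 technical explanations, and a difference in where ribosomal proteins are translated may remain as a hypothesis that was not tested.

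With 3 libraries against 3, or 3 same-numbered pairs of libraries against 3 for the difference of enrichments, not known to share a lysate, 10 splits are possible, too few for a share under 0.05. ER against cytosol ribosome-bound RNA gave 8699 genes against at most 0 in the other splits (1 split of 10 as large), ER ribosome-bound against whole-cell RNA 10238 against 0 (1 of 10), cytosol ribosome-bound against whole-cell RNA 8741 against 0 (1 of 10), ER against cytosol whole-cell RNA 0 against 1 (10 of 10), and the difference of enrichments 7033 against 0 (1 of 10). These are counts by edgeR's quasi-likelihood test. Every other split mixes libraries of both real groups, so a true difference enters the spread within groups and few calls follow. Where the groups differ, the 0 calls of the other splits are therefore no separate evidence.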

How the results depend on the processing

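A result counted as the same if it kept its direction and side of the threshold, or passed the threshold in neither fit. Of 179 values of genes named by the rule, 179 were the same with limma-voom, 177 with DESeq2, 178 with RLE size factors and 175 with no filter on low counts. The count was 171 with a minimum of 5 CPM, 166 with cytosolic scaling and 105 when tested against a 2-fold change. It was 169 of 172 with mitochondrially encoded genes left out, 160 of 162 with only the groups compared, and 175 to 179 without any 1 library. Of 145 list results, 112 were the same with an estimated correlation, 109 with fry, 135 with cytosolic scaling, and 136 to 139 without a replicate number. The test with an estimated correlation of the segment classes was added after seeing the data; all other alternatives were planned. At this depth the self-test recovered 72% of genes changed 1.5-fold between both ribosome-bound groups, so smaller changes can be missed.

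Cytosolic scaling gave 7301 genes higher and 933 lower on ER-labelled than on cytosol-labelled ribosomes, 8430 and 2257 on ER-labelled ribosomes against whole-cell RNA, and 6123 and 468 for the difference of enrichments, by its construction as a shift of all genes. It turned the log2 change between both ribosome-bound groups to 0.16 for Shmt2, 0.19 for Rpl7a and 0.18 for Ndufs1, and that of ER-labelled ribosomes over whole-cell RNA to 0.16 for Rpl31, 0.22 for Lama5, 0.24 for Ddit3 and 0.21 for Rps9. Tested against a 2-fold change, a stricter hypothesis, 2317 genes were higher and 0 lower between both ribosome-bound groups (glmTreat; 6 lower at an unadjusted p under 0.05), 1820 and 159 on ER-labelled ribosomes against whole-cell RNA, 114 and 286 on cytosol-labelled ribosomes, and 2103 and 1 for the difference (Gm13410, named after its value was seen, at -2.56). With no filter 7 genes were lower in ER than in cytosol whole-cell RNA, against 0 in edgeR's test with the filter (278 lower at an unadjusted p under 0.05; 0 by DESeq2 and limma-voom), and a minimum of 5 CPM put Psma3 at 0.08 on cytosol-labelled ribosomes. The 7 genes were highest in cytosol replicate 2 among whole-cell libraries; why the filter changed their test was not tested, nor was the cause for Psma3.

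With an estimated correlation, which widens the null for lists whose genes vary together, 1 list was lower between both ribosome-bound groups, 2 on ER-labelled ribosomes against whole-cell RNA, 7 on cytosol-labelled ribosomes with 1 higher, 1 for the difference, and 0 higher between whole-cell groups. Fry, which asks another question, called 11 lists lower on ER-labelled and 20 on cytosol-labelled ribosomes against whole-cell RNA and 0 higher between whole-cell groups. Among results that camera or fry called, the signs of both tests differed for 3, all against whole-cell RNA. These were interferon-stimulated genes on ER-labelled ribosomes (median -0.09), and GPI-anchored proteins (0.05) and cytosolic chaperones (-0.04) on cytosol-labelled ribosomes. Between whole-cell groups, cytosolic scaling gave 0 lists higher and 1 lower. Stricter segment thresholds, which move genes between classes, gave 0.50 for the single internal class and 0.11 for the C-terminal class. Rpl31 was at 0.07 between both ribosome-bound groups without mitochondrially encoded genes. Its difference of enrichments was at 0.11 with RLE and 0.10 without those genes. List medians moved by similar amounts. Between both ribosome-bound groups without those genes, ER chaperones went from 2.25 to 2.19 and ribosomal proteins from 0.17 to 0.11. The shift was thus not particular to Rpl31.

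Equal replicate numbers are not stated to mark the same lysate. Each library's deviations from the mean log2 CPM of its group were therefore correlated across genes. By these deviations, ribosome-bound and whole-cell libraries of a targeting correlated best with their own number in 4 of 6 cases (same-number values -0.01 to 0.26). Libraries of different targetings did so in 0 of 6. With a block for the number, 4595 genes were higher and 3848 lower between both ribosome-bound groups, and 2 lists higher between whole-cell groups.

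Leaving out libraries or replicate numbers gave 4029 to 4718 genes higher and 3465 to 5137 lower between both ribosome-bound groups, 4674 to 5307 and 4430 to 5010 on ER-labelled ribosomes against whole-cell RNA, 2721 to 4227 and 4182 to 5326 on cytosol-labelled ribosomes, 0 to 0 and 0 to 2 between whole-cell groups (2 without cytosol whole-cell replicate 3), and 3436 to 3961 and 2374 to 3820 for the difference. Lists called numbered 11 to 11 higher and 8 to 9 lower, 11 to 11 and 6 to 6, 4 to 5 and 13 to 13, 0 to 5 and 0 to 3, and 10 to 11 and 7 to 8 in the same order. Rpl31 was at 0.06 to 0.13, -0.11 to -0.06, -0.24 to -0.17, -0.09 to 0.00 and 0.06 to 0.16. Between whole-cell groups, leaving out a replicate number gave medians of -0.02 to 0.06 for lysosomal proteins and -0.01 to 0.03 for translation factors (both lowest without number 2), and -0.07 to 0.02 for ribosomal proteins and -0.04 to 0.02 for respiratory chain subunits (both highest without number 3). mt-Nd2 between both ribosome-bound groups was at -0.21 to 0.19, lowest without number 3. Fewer samples were fitted in each case.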

Other observations

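Some genes without a predicted hydrophobic segment were higher on ER-labelled than on cytosol-labelled ribosomes. All genes in this paragraph except Grn and Serpine2, which the rule also named, were chosen after their values were seen. The small GTPases Sar1b and Sar1a, which act in the budding of vesicles from the ER, had log2 changes of 1.66 (SE 0.043, n = 3) and 1.18 (SE 0.036), and Srpr, the receptor subunit for the signal recognition particle, 1.56 (SE 0.039). Arl1, a Golgi GTPase, was at 1.30 (SE 0.044), Faf2, a factor of ER-associated degradation, at 1.36 (SE 0.042), and Akap1, an anchor protein of the outer mitochondrial membrane, at 1.26 (SE 0.036). Against whole-cell RNA, Akap1 was at -0.11 (SE 0.034) on ER-labelled and -1.37 (SE 0.036) on cytosol-labelled ribosomes, so it was not enriched at the ER. Sar1b, Sar1a, Srpr, Arl1 and Faf2 were at 0.99 to 1.7 on ER-labelled ribosomes against whole-cell RNA. Of the no-segment genes with a mean of at least 10 CPM, 38 passed the test against a 2-fold change. Several of these, such as Grn and Serpine2, encode proteins known to enter the secretory pathway whose signal peptide the predictor missed. Not all of the 38 are of this kind, and the transcription factor Foxh1 was among them at 1.34 (SE 0.044).

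By number of segments, leaving out proteins with an N-terminal segment or with a single segment at the C terminus, and genes under 10 CPM, the median log2 change of ER-labelled over cytosol-labelled ribosomes was -0.13 for 6257 genes without a segment, a sign that depends on the scaling, 0.02 for 852 genes with 1, 0.30 for 252 with 2, 1.14 for 113 with 3, 1.32 for 83 with 4, 1.56 for 56 with 5 and 1.47 for 191 with at least 6. Classes with few segments mix membrane proteins with cytosolic proteins in which the predictor found a segment, such as Cct8 and Psmd2. A graded effect of segment number can therefore not be read from these medians. Jun and Junb, which form AP-1 transcription factors, and the kinase Plk2 were higher on both kinds of ribosomes than in whole-cell RNA. Jun was named by the rule on cytosol-labelled ribosomes, and Junb and Plk2 were chosen after their values were seen. Jun was at 1.20 on ER-labelled and 1.06 on cytosol-labelled ribosomes, Junb at 1.02 and 0.80 and Plk2 at 0.78 and 0.85.

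The tests of both patterns that follow were chosen only after the result was seen. mRNAs with long coding sequences were lower on ribosomes than in whole-cell RNA. Among genes without a segment and with at least 10 CPM, the median log2 change was 0.03 on ER-labelled and 0.12 on cytosol-labelled ribosomes for 575 genes with up to 0.5 kb, and -0.84 and -1.05 for 33 genes with over 8 kb, among them Dync1h1, chosen after its values were seen, at -1.89 and -2.34. RNA breakage before poly(A) selection would act on 3' UTR length as on coding length. On ER-labelled ribosomes the slope per kb of 3' UTR was 0.12 of that per kb of coding sequence (95% interval over resampled genes 0.06 to 0.42). It was measured in 2563 genes whose annotated transcripts have 3' UTR lengths within 100 nt of each other, which a gene with a single annotated coding transcript meets by definition. On cytosol-labelled ribosomes the ratio was 0.09. Over all 6257 genes it was 0.19 (0.1 to 0.4) on ER-labelled and 0.16 on cytosol-labelled ribosomes. The slope on 3' UTR length was itself negative over these genes, at -0.021 per kb on both kinds of ribosomes. Its interval was -0.043 to -0.011 for the ER and -0.045 to -0.011 for the cytosol. GC content went with the change too, from a median of -0.26 on ER-labelled ribosomes in the lowest of 5 GC bins to -0.05 in the highest, but adding it left the slope on coding length at 1.00 (0.99 to 1.02) of its value without it, and within bins the slope was -0.130 to -0.098 per kb. These values argue against GC content. They do not exclude breakage as a part of the pattern, since longer 3' UTRs also went with lower levels. Errors in annotated 3' UTR length would also lower that slope. Loss of long mRNAs with many ribosomes during purification, or a lower share of them on ribosomes, may remain too, and neither was tested.

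Markers of the 2-cell-like state were higher on both kinds of ribosomes than in whole-cell RNA (adjusted p = 0.12 for the ER and 0.019 for the cytosol with an estimated correlation). Reads moved between near-identical Zscan4 copies, if still counted, would leave the sum of the family unchanged. The summed level of its 9 members was higher on ribosomes by 2.37 (single libraries 2.20 to 2.48) on the log2 scale in the targeting with the smaller ratio. This was the ER, at 67.64 ± 1.04 CPM (SD, n = 3) against 13.06 ± 1.26 CPM. Reads that matched several copies may have been left out of the counts, and the sum cannot show such a loss. The list lay 1.98 above 1524 genes without a segment in its range of coding length and mean CPM (95% interval over resampled genes 1.46 to 2.39). Only the ranges were matched, and mean CPM includes the ribosome-bound libraries, where the list is high. The level in whole-cell RNA was thus not matched, and the interval treats near-identical genes as independent. These values argue against reads moved among counted copies and against coding length within that range. Loss of reads from the counts and a low level in whole-cell RNA were not excluded. Labelled ribosomes come only from cells that took up the plasmids, while whole-cell RNA comes from all cells, so a difference between these cells may remain as an explanation and was not tested.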
